A study of Mus musculus with 9 samples.

How the data were processed

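Per the labels, bulk directional RNA-seq was made from 1 µg of total RNA of mouse intestinal organoids and tumoroids of 3 genotypes (WT, A and AKSP), 3 libraries each, 9 in all. The estimated count of each gene in each library is a deposited value that the authors made without scaling between libraries. The other deposited table holds a signal per gene and library, which matches the rounded estimated count divided by 1 factor per library (0.200 to 1.24) for 100% of values in 8 libraries and 99.996% in A 3. Those factors were 0.847 to 0.903 times the median-of-ratios factors of these 9 libraries. Multiplying back gave whole numbers for 100% of values (tolerance 0.01). The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.6, STAR 2.7.5b, Salmon 1.2.1, DESeq2 1.30.1 and the builds mm10 and GRCm38. Coordinates, GC content and transcript length were taken from GENCODE M21, whose identifiers matched 98.1% of the 54347 genes with version and 99.5% without. The annotation release that the authors used is not given in the sources used here.

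The estimated counts, of which 7.56% to 15.6% per library were not whole, were rounded. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16698, and libraries were scaled by TMM. All 9 libraries were fitted together by group with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, for A vs WT, AKSP vs WT and AKSP vs A, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its absolute value divided by the square root of F. Levels are CPM (edgeR cpm with the TMM library sizes) as mean ± SD. Where the lower group had 0 counts, the fold is a lower limit from a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with a 95% counting interval.

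Of 36 gene lists, 11 primary and 25 secondary, each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. A list passed, or was called, on camera at the preset correlation. The fry p was not adjusted over the lists and is not part of the ranges of alternatives. Members were counted at the adjusted p over all genes and also adjusted over the list alone. The named genes followed a rule: the 4 targeted genes, the 6 largest increases and the 6 largest decreases per comparison, 2 genes per primary list, and 1 gene per secondary list with at least 3 members called. The largest changes needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a predicted gene, clone or pseudogene name. Further list members were named after their values were seen, as members that went against their list or as examples of it. Cdkn1a was among these.

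The labels give replicate numbers without saying what they stand for. After the group means were removed, the same-numbered libraries of AKSP and A correlated at 0.271, 0.457 and 0.205, all above 0.1, so that comparison was also fitted with a replicate block. The block was fitted over all 9 libraries, so the WT libraries also entered its replicate effects. On simulated data with 50 changed genes per fold size, the test recovered 2%, 0% and 6% of genes at a log2 fold change of 1 in A vs WT, AKSP vs WT and AKSP vs A, 52%, 54% and 50% at 2, and 94%, 96% and 98% at 4. False calls were 2 of 124, 4 of 131 and 8 of 139. Far fewer genes were changed than were called in the data, which makes the adjusted p stricter in the simulation. The common biological coefficient of variation was 41.1%. Log2 CPM used a prior count of 2. The alternatives were other scaling, filters and tests (DESeq2 1.42.0, limma), the replicate block, a fit of only the 2 groups compared, a fold threshold, and leaving out each library. Added after the results were seen were the recovered reads, limma-voom with sample quality weights, autosomal genes alone, offsets for GC content and length with and without the block, and list counts without WT 2 or AKSP 2. Pairs of replicate libraries correlated at 0.904 to 0.984, and no library duplicated another. Of the symbols, 105 occur more than 1 time, and genes were handled by identifier.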

Results

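Messenger RNA was measured by directional bulk RNA-seq in mouse intestinal epithelial organoids, cultures that hold stem cells and their differentiated progeny, and in tumoroids derived from such epithelium by engineered mutations. The 9 libraries form 3 genotypes with 3 libraries each. Per the labels, WT stands for wild-type organoids, A for tumoroids with Apc knocked out, and AKSP for tumoroids with Apc, Smad4 and Trp53 knocked out and a mutant Kras allele. Apc restrains Wnt signalling, Kras acts upstream of the ERK pathway, Smad4 carries TGF-beta and BMP signals to the nucleus, and Trp53 encodes the stress-response factor p53. All cultures were harvested at confluence. The libraries are named by genotype and replicate number, WT 1 to AKSP 3. The total estimated counts were 41623655, 13355174 and 46590863 in WT 1, WT 2 and WT 3, 47931162, 47837827 and 43403055 in the A libraries, and 52168303, 40542512 and 45728527 in the AKSP libraries. WT 2 stood apart from WT 1 and WT 3: it detected 17690 genes against 22072 and 21167, and genes for ribosomal proteins took 22.2% of its counts against 8.33% and 9.51%. The first principal component held 62.2% of the variance, the second 13.8% and the third 11.1%. Sex-linked genes separated the WT libraries from both tumoroid lines. Xist, the RNA that silences an X chromosome in female cells, stood at 1543, 365 and 124 CPM (counts scaled by library size) in WT 1, WT 2 and WT 3 and at or under 0.201 CPM in every A and AKSP library. Kdm5d, a Y-linked histone demethylase, had 0 or 1 counts per WT library, 39.9 ± 6.89 CPM (SD, n = 3) in A and 16.6 ± 1.74 CPM (SD, n = 3) in AKSP. The 2 comparisons with WT are also comparisons between libraries of different sex-linked expression. The p-values measure only the spread between these libraries, since the labels do not say that they came from separate cultures or animals. Counting intervals and floors cover counting error only.

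**Figure D1:**
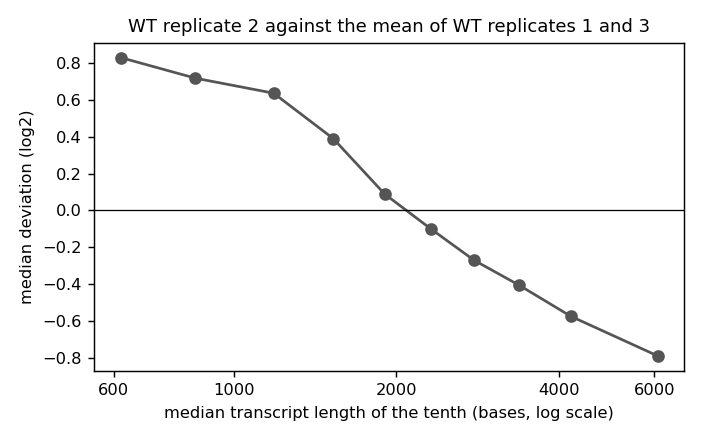
Median log2 deviation of WT 2 from the mean of WT 1 and WT 3 (vertical axis) for genes divided into 10 groups by transcript length (horizontal axis, bases, log scale). It went from 0.830 in the shortest group (median 618 bases) to -0.791 in the longest (6088 bases).

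The engineered genes were examined first. Smad4 (ENSMUSG00000024515.13, chromosome 18, positions 73639009 to 73703780 of GRCm38) fell in AKSP to 19.4 ± 4.40 CPM (SD, n = 3), from 79.4 ± 9.08 CPM (SD, n = 3) in WT (log2 fold change -2.03, SE 0.23, adjusted p = 1.7e-04) and 100.2 ± 5.04 CPM (SD, n = 3) in A (log2 fold change -2.37, SE 0.24, adjusted p = 9.4e-04). Trp53 (ENSMUSG00000059552.13, chromosome 11, positions 69580359 to 69591873) was at 112 ± 21.6 CPM (SD, n = 3) in WT, 186 ± 22.0 CPM (SD, n = 3) in A and 85.2 ± 15.5 CPM (SD, n = 3) in AKSP, and it fell between A and AKSP (log2 fold change -1.12, SE 0.24, adjusted p = 0.0255). That call was lost at adjusted p = 0.0628 without A 1, 0.0911 without A 2, 0.109 without A 3, 0.0717 without AKSP 1, 0.0651 without AKSP 2 and 0.0814 without AKSP 3, and at 0.0866 with library totals, in a range over its alternatives of 4.1e-04 to 0.109. Trp53 was not called in AKSP vs WT (log2 fold change -0.40, adjusted p = 0.208). In A vs WT, Trp53 missed the threshold (log2 fold change 0.73, adjusted p = 0.0507), passing at adjusted p = 0.0484 without WT 3 and 0.0420 without AKSP 2, at 0.0349 with DESeq2, 0.0328 with GC and length offsets, 0.0108 with quality weights and 0.0497 with autosomal genes alone, in a range of 0.0108 to 0.175. Apc (ENSMUSG00000005871.15, chromosome 18, positions 34220924 to 34322552) had more transcript in the tumoroids than in WT: 23.7 ± 18.4 CPM (SD, n = 3) in WT, 97.0 ± 69.2 CPM (SD, n = 3) in A and 129.9 ± 11.9 CPM (SD, n = 3) in AKSP. Smad4 was not called in A vs WT (log2 fold change 0.33, adjusted p = 0.307), and Apc was not in AKSP vs A (log2 fold change 0.42, adjusted p = 0.793). The rise of Apc passed in AKSP vs WT (log2 fold change 2.45, SE 0.61, adjusted p = 0.0113, moved to 3.34 without WT 1) and in A vs WT (log2 fold change 2.03, SE 0.60, adjusted p = 0.0348, moved to 2.91 without WT 1 and 1.27 without A 1). In A vs WT the Apc call was lost at adjusted p = 0.0886 without WT 2, 0.0802 without WT 3, 0.143 without A 1, 0.0540 without A 3, 0.0533 without AKSP 1, 0.0513 without AKSP 2 and 0.0532 without AKSP 3, and at 0.083 when only the 2 groups entered the fit, in a range of 0.00347 to 0.143. Kras (ENSMUSG00000030265.14, chromosome 6, positions 145216699 to 145250239) stood at 57.4 ± 12.8 CPM (SD, n = 3) in WT, 76.0 ± 13.7 CPM (SD, n = 3) in A and 75.9 ± 3.20 CPM (SD, n = 3) in AKSP, with no call in any comparison (adjusted p = 0.240, 0.202 and 1). How the alleles were made is not given in the sources used here.

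**Figure D2:**
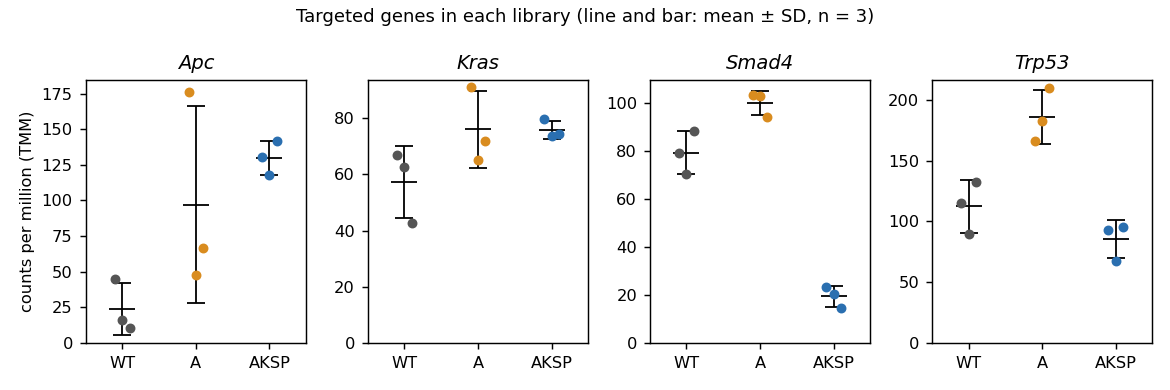
Level of the 4 engineered genes in CPM (vertical axes, from 0) in each of the 9 libraries (points), with the mean and SD of each genotype. Smad4 was lower in the 3 AKSP libraries (mean 19.4) than in every WT and A library, and Kras was not called in any comparison.

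A vs WT compares tumoroids engineered at Apc with wild-type organoids, which also differ from them in sex-linked expression. Most transcripts of mature absorptive cells were lower in A. Apoa4, an apolipoprotein of lipid-absorbing enterocytes, stood at 1029 ± 172 CPM (SD, n = 3) in WT and at 3 counts in all over the A libraries (ratio 54090, 95% counting interval 18510 to 262300). Fabp1, which binds fatty acids in enterocytes, went from 883 ± 417 CPM (SD, n = 3) to 0.0407 ± 0.00159 CPM (SD, n = 3) (log2 fold change -14.31, SE 0.61, adjusted p = 1.1e-05). Apoc3, another apolipoprotein, and Cfhr2, a relative of complement factor H, had 0 counts in A and were at least 2789-fold and at least 2915-fold lower against a floor of 3 counts over the group. Without WT 2 their log2 fold changes moved from -14.84 to -14.16 and from -13.97 to -14.63. Cyp2c66, a cytochrome P450, fell as well (ratio 22210, 95% counting interval 7598 to 107700). Of the 26 enterocyte markers tested, 0 rose and 23 fell, and also 23 adjusted over the list alone. Camera gave the enterocyte list adjusted p = 1.7e-18, alternatives from 1.5e-21 up to adjusted p = 0.0943 with an estimated correlation. Most enteroendocrine markers and 8 of 17 goblet cell markers fell too. Among 22 enteroendocrine markers, 0 rose (1 without WT 2) and 14 fell (9 without A 2). That became 1 and 16 adjusted over the list alone. Camera gave the enteroendocrine cell list adjusted p = 1.8e-07, alternatives from 9.1e-09 up to adjusted p = 0.254 with an estimated correlation. The hormone gene Sst had 0 counts in A, at least 592-fold lower (log2 fold change -12.69, moved to -11.85 without WT 2). Gip went from 131 ± 143 CPM (SD, n = 3) to 0.734 ± 0.198 CPM (SD, n = 3) (log2 fold change -7.48, adjusted p = 4.2e-04, moved to -6.12 without WT 2). Among 17 goblet cell markers, 8 fell (5 without A 1 and 3 without A 3), among them Muc2, the main intestinal mucin (log2 fold change -3.71, adjusted p = 0.00854, moved to -4.42 without A 3), and Spink4 (log2 fold change -4.45, adjusted p = 0.0116, moved to -2.73 without WT 2, lost at 0.0505 without A 1 and 0.0545 without A 3, range 1.9e-06 to 0.0545). Bcas1 went against the list and rose (log2 fold change 2.20, 1 member, 2 without WT 2), and the counts were 1 and 10 adjusted over the list alone. Camera gave the goblet cell list adjusted p = 0.0119, alternatives from 0.00330 up to adjusted p = 0.507 with an estimated correlation. Markers of the small intestine fell in 8 of 14 cases and rose in 0. That became 9 and 0 adjusted over the list alone. Camera gave the small intestine region list adjusted p = 1.2e-04, alternatives from 3.2e-05 up to adjusted p = 0.103 with an estimated correlation. Colon markers fell in 3 of 7 cases, the same number adjusted over the list alone, among them the anion exchanger gene Slc26a3 (log2 fold change -5.34, adjusted p = 5.5e-04, moved to -4.49 without WT 1); the list passed. Camera gave the colon region list adjusted p = 0.0465, alternatives from 0.0338 up to adjusted p = 0.211 with an estimated correlation, lost at 0.0642 without WT 1, 0.0951 without WT 3, 0.0585 without A 1 and 0.0705 with GC and length offsets.

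Crypt cell markers moved both ways in A vs WT. Olfm4, a marker of stem cells in the small intestinal crypt, went from 448 ± 223 CPM (SD, n = 3) to 0.442 ± 0.213 CPM (SD, n = 3) (log2 fold change -9.98, SE 1.14, adjusted p = 2.4e-04), while Tnfrsf19, a Wnt-induced receptor, rose from 3.37 ± 0.994 CPM (SD, n = 3) to 138 ± 40.5 CPM (SD, n = 3) (log2 fold change 5.39, SE 0.46, adjusted p = 4.8e-05). Over 20 crypt stem cell markers, 4 rose (2 without A 3) and 5 fell (3 without WT 2, 2 without A 1, 3 without A 2 and 2 without A 3), or 4 and 7 adjusted over the list alone, and the list did not pass. Camera gave the crypt stem cell list adjusted p = 0.656, alternatives from 0.525 to 0.933, and adjusted p = 0.877 with an estimated correlation. The Paneth cell list did not pass either. Camera gave the Paneth cell list adjusted p = 0.173, alternatives from 0.0716 up to adjusted p = 0.772 with an estimated correlation. In it 2 rose (1 without WT 1, 0 without WT 3, 0 without A 2 and 0 without A 3) and 5 fell (9 without WT 1, 2 without WT 2, 8 without WT 3, 2 without A 1, 3 without A 2, 2 without A 3 and 8 without AKSP 3) of 17. That became 2 and 9 adjusted over the list alone. The pentraxins Mptx1 and Mptx2 were among those that fell (log2 fold change -6.69, adjusted p = 0.00308, moved to -7.32 without WT 2 and -6.00 without WT 3 and log2 fold change -6.05, adjusted p = 0.00226, moved to -6.65 without WT 2 and -5.42 without WT 3). WT 2 carried the Paneth markers at a higher level than WT 1 and WT 3, with a median deviation of 2.34 (log2).

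Several groups of genes rose in A. Wnt target genes were among them: 10 of 22 rose and 0 fell. That became 11 and 0 adjusted over the list alone. Camera gave the Wnt/beta-catenin targets list adjusted p = 3.7e-05, alternatives from 8.4e-06 up to adjusted p = 0.211 with an estimated correlation. They included the feedback gene Axin2 (log2 fold change 1.99), the homeobox gene Prox1 (log2 fold change 4.53, adjusted p = 0.00153, moved to 5.38 without WT 1), and Ccnd1 and Cd44, a cyclin and an adhesion receptor (log2 fold changes 3.03 and 2.81). Every tested gene of the fetal-like and regenerative epithelium list rose, 22 of 22, also adjusted over the list alone. Camera gave the fetal-like and regenerative epithelium list adjusted p = 3.5e-14, alternatives from 4.0e-16 up to adjusted p = 0.103 with an estimated correlation. Tacstd2, a surface glycoprotein of fetal intestinal progenitors, went from 0.886 ± 0.817 CPM (SD, n = 3) to 105 ± 20.9 CPM (SD, n = 3) (log2 fold change 7.19, SE 0.66, adjusted p = 7.2e-05, moved to 7.91 without WT 2), and the keratin gene Krt4 rose with it (log2 fold change 6.67, adjusted p = 1.4e-04). Targets of the growth regulators YAP and TAZ rose in 16 of 21 cases and fell in 0. That became 17 and 1 adjusted over the list alone. Camera gave the YAP/TAZ targets list adjusted p = 5.0e-09, alternatives from 1.7e-09 up to adjusted p = 0.0265 with an estimated correlation. This was the 1 list of the 15 called in A vs WT that kept its call with an estimated correlation. Ptpn14, a phosphatase gene that YAP induces, rose from 1.96 ± 0.159 CPM (SD, n = 3) to 107 ± 13.3 CPM (SD, n = 3) (log2 fold change 5.78, SE 0.27, adjusted p = 6.8e-06). ERK output genes rose in 15 of 23 cases, with Fosl1, an AP-1 subunit, and Il1rn, the interleukin-1 receptor antagonist, at the top (log2 fold change 4.66, adjusted p = 3.0e-05 and log2 fold change 4.58, adjusted p = 4.6e-05). In that list 1 fell (0 without WT 3, 0 without A 1, 0 without A 2, 0 without A 3 and 0 without AKSP 1), the early growth response gene Egr1 (log2 fold change -1.09), and 18 and 1 passed adjusted over the list alone. Camera gave the ERK pathway output list adjusted p = 2.2e-06, alternatives from 1.4e-06 up to adjusted p = 0.103 with an estimated correlation. Keratins and cornification genes of stratified epithelium rose in 10 of 12 cases, also 10 adjusted over the list alone. Camera gave the squamous epithelium list adjusted p = 1.8e-06, alternatives from 3.4e-07 up to adjusted p = 0.0943 with an estimated correlation. Krt16 had 3 counts over the WT libraries (ratio 51.5, 95% counting interval 17.4 to 252). Stomach epithelium genes such as Vsig1, an adhesion molecule (log2 fold change 4.32, adjusted p = 8.4e-05), rose in 6 of 12 cases, 0 fell (1 without WT 2), and 7 rose adjusted over the list alone. Camera gave the gastric epithelium list adjusted p = 0.00390, alternatives from 0.00107 up to adjusted p = 0.279 with an estimated correlation.

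Some p53 targets rose in A, where the labels name no change to Trp53. Of 30 targets, 14 rose and 1 fell (0 without WT 1, 0 without WT 3, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 2 and 0 without AKSP 3). That became 16 and 2 adjusted over the list alone. Camera gave the p53 targets list adjusted p = 5.6e-04, alternatives from 8.2e-05 up to adjusted p = 0.103 with an estimated correlation. The gene that fell was Pltp, a phospholipid transfer protein (log2 fold change -2.05). Those that rose included Mdm2, whose product degrades p53, and the cyclin gene Ccng1 (log2 fold changes 2.01 and 2.22), the kinase gene Plk2 (log2 fold change 3.43, adjusted p = 2.2e-04) and the receptor gene Eda2r (log2 fold change 3.43, adjusted p = 0.00480, moved to 4.14 without WT 1). BMP targets gave 4 that rose and 1 that fell (2 without WT 1) of 11, the same adjusted over the list alone, and no call for the list. Camera gave the BMP-SMAD targets list adjusted p = 0.223, alternatives from 0.0721 up to adjusted p = 0.693 with an estimated correlation. Id2, an inhibitor of helix-loop-helix factors, rose (log2 fold change 1.84, adjusted p = 7.4e-04), as did Id3 (log2 fold change 1.72, adjusted p = 0.0266, lost at 0.0545 without WT 1, 0.0754 without WT 3, 0.0904 without A 2 and 0.103 without A 3 and at 0.0527 with only the 2 groups fitted, range 0.00195 to 0.103), while Smad6, an inhibitor of the same pathway, fell (log2 fold change -3.08). TGF-beta targets gave 5 that rose and 2 that fell (1 without WT 1, 1 without WT 3, 1 without A 1, 1 without A 2, 1 without A 3, 1 without AKSP 1 and 1 without AKSP 3) of 14, or 6 and 2 adjusted over the list alone, also with no call for the list. Camera gave the TGF-beta-SMAD targets list adjusted p = 0.136, alternatives from 0.0700 up to adjusted p = 0.507 with an estimated correlation. Col4a1, a basement membrane collagen, rose from 1.85 ± 0.827 CPM (SD, n = 3) to 379 ± 131 CPM (SD, n = 3) (log2 fold change 7.69, SE 0.52, adjusted p = 1.9e-05). Serpine1, a protease inhibitor, rose as well (log2 fold change 4.91, adjusted p = 0.0338, moved to 6.19 without WT 3 and 4.29 without A 3, lost at 0.0763 without WT 1, 0.0926 without WT 2, 0.0676 without A 2 and 0.0907 without A 3 and at 0.0887 with quality weights, range 0.00104 to 0.0926), and the matrix genes Tgfbi and Timp3 fell (log2 fold changes -1.61 and -3.78). Genes of oxidative phosphorylation, such as Sdhb of respiratory complex II (log2 fold change -1.83, adjusted p = 0.00553), gave 15 that fell (5 without A 1, 5 without A 2 and 4 without A 3) and 0 that rose of 22. That became 20 and 0 adjusted over the list alone. Camera gave the oxidative phosphorylation list adjusted p = 2.3e-06, alternatives from 7.1e-08 up to adjusted p = 0.335 with an estimated correlation. WT 2 was high in this list, with a median deviation of 0.873 (log2) from WT 1 and WT 3. Without it 18 members fell and the median log2 fold change of the list went from -1.29 to -0.80. Mitochondrially encoded messages gave 5 that fell (1 without A 2 and 2 without A 3) and 0 that rose of 13, also 5 adjusted over the list alone. Camera gave the mitochondrially encoded mRNA list adjusted p = 0.0174, alternatives from 5.6e-04 up to adjusted p = 0.501 with an estimated correlation, lost at 0.112 without WT 1, 0.0619 without A 2 and 0.0757 with GC and length offsets. The message mt-Nd3, a complex I subunit, went from 1017 ± 673 CPM (SD, n = 3) to 211 ± 112 CPM (SD, n = 3) (log2 fold change -2.27, adjusted p = 0.00994, moved to -1.63 without WT 2).

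Over all genes, A vs WT called 4084 of the 16698 tested, 2197 higher and 1887 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05); without A 3 the count was 2503. Which direction held more calls varied: 2032 were higher and 2409 lower with GC and length offsets, 1663 and 1959 without WT 3, and 2603 and 2634 with DESeq2, against 2380 and 1417 with library totals. The lower genes numbered 1108, 1161 and 996 without A 1, A 2 and A 3. The libraries of A and WT did not overlap for 44.5% of genes, against 10% by chance. Beside the genes above, the largest increases that met the naming rule were in the Y-linked genes Ddx3y (0 counts in WT, at least 1177-fold higher), Eif2s3y (ratio 6667, 95% counting interval 1196 to 263300), Uty (ratio 1467, 95% counting interval 263 to 57980) and Kdm5d (ratio 1975, 95% counting interval 546 to 16310), in Ly6g, a gene of the Ly6 surface antigen family that had 0 counts in WT (at least 196-fold higher), and in Nebl, which encodes the actin-binding protein nebulette (ratio 964, 95% counting interval 329.5 to 4675). The folds of Ddx3y and Uty leaned on A 1: in A 1, A 2 and A 3 they stood at 78.5, 19.6 and 9.53 CPM and at 26.8, 9.37 and 8.58 CPM. Xist was among the 6 largest decreases (log2 fold change -13.38, adjusted p = 1.1e-04, moved to -11.86 without WT 1), and the sex-linked list passed with 4 members higher and 1 lower of 5, the same adjusted over the list alone. Camera gave the sex-linked list adjusted p = 0.00154, alternatives from 3.7e-04 up to adjusted p = 0.274 with an estimated correlation. Across genes, the fold changes correlated with transcript length at Spearman 0.376. Krt20, a keratin of mature intestinal cells, fell (log2 fold change -3.10, adjusted p = 7.9e-04), as did H2-Ab1, an MHC class II chain (ratio 90.2, 95% counting interval 30.4 to 442). Single genes from further lists were the protease gene Mmp14 (log2 fold change -6.82, adjusted p = 8.7e-06), the glutathione transferase gene Gsta1 (log2 fold change -2.72, adjusted p = 0.00153), the amino acid transporter gene Slc7a5 (log2 fold change 1.85, adjusted p = 0.00213), the heat shock gene Hspa1b (log2 fold change 3.07, adjusted p = 1.6e-04) and Ptgs1, a cyclooxygenase of tuft cells (ratio 539, 95% counting interval 184 to 2613). The falls of Mmp14, Gsta1 and Krt20 were not typical of their lists, which did not pass. In the epithelial-mesenchymal transition list of Mmp14, 4 rose and 3 fell of 12. The NRF2 target list of Gsta1 gave 5 and 3 of 17, and the epithelial junction and keratin list of Krt20 gave 6 and 3 of 17. Ptgs1 went against its list: among 10 tuft cell markers 2 rose (1 without WT 1, 1 without WT 3, 1 without A 2 and 1 without A 3) and 3 fell, or 2 and 4 adjusted over the list alone, and the list did not pass. Camera gave the tuft cell list adjusted p = 0.253, alternatives from 0.184 to 0.593, and adjusted p = 0.575 with an estimated correlation. Psmb8, an immunoproteasome subunit, fell (log2 fold change -3.76, adjusted p = 0.0121, lost at 0.0531 without A 3, range 2.9e-05 to 0.0531).

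**Figure D3:**
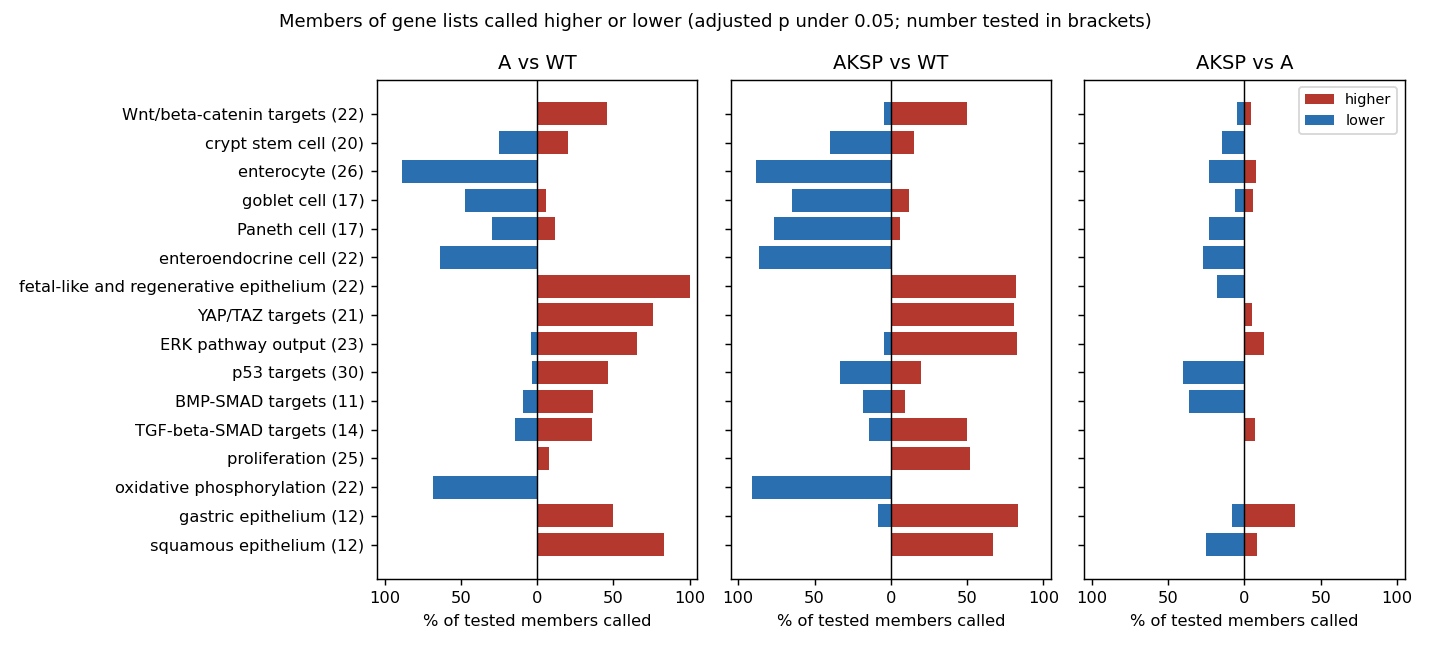
Percentage of the tested members of 16 gene lists (vertical axis, number tested in brackets) called higher (red, right) or lower (blue, left) in each comparison, at adjusted p under 0.05. All 22 fetal-like genes were higher in A vs WT and 23 of 26 enterocyte genes lower, and in AKSP vs A 12 of 30 p53 targets were lower.

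AKSP vs WT compares tumoroids labelled with all 4 alterations with the same wild-type organoids, with the same difference in sex-linked expression. The loss of differentiated cell transcripts was broad. Fabp1 had 0 counts in AKSP, at least 34680-fold lower than in WT, and so had Btnl1, a butyrophilin-like gene of gut epithelium, and Ugt2a3, a glucuronosyltransferase gene, at least 4639-fold and at least 2901-fold lower. Cyp2c66 had 1 count over the AKSP libraries (ratio 66590, 95% counting interval 11950 to 2630000), and Apoa4 and Cyp2c29 were also among the 6 largest decreases (log2 fold change -14.29, adjusted p = 7.3e-06, moved to -16.35 without AKSP 2 and log2 fold change -13.70, adjusted p = 2.3e-05, moved to -14.81 without AKSP 1). Enterocyte markers fell in 23 of 26 cases and rose in 0. That became 24 and 0 adjusted over the list alone. Camera gave the enterocyte list adjusted p = 5.3e-16, alternatives from 2.2e-18 up to adjusted p = 0.142 with an estimated correlation. Enteroendocrine markers fell in 19 of 22 cases and rose in 0. That became 21 and 0 adjusted over the list alone. Camera gave the enteroendocrine cell list adjusted p = 8.1e-11, alternatives from 5.4e-13 up to adjusted p = 0.195 with an estimated correlation. Paneth cell markers fell in 13 of 17 cases, also 13 adjusted over the list alone. Camera gave the Paneth cell list adjusted p = 1.3e-04, alternatives from 6.0e-06 up to adjusted p = 0.337 with an estimated correlation. Mptx1, a pentraxin gene, went from 44.9 ± 39.4 CPM (SD, n = 3) to 0.0589 ± 0.0729 CPM (SD, n = 3) (log2 fold change -9.59, SE 1.43, adjusted p = 7.3e-04, moved to -10.23 without WT 2, -8.89 without WT 3 and -11.02 without AKSP 2), whereas the phospholipase gene Pla2g2a went against the list and rose (log2 fold change 4.73). Goblet cell markers fell in 11 of 17 cases, 12 adjusted over the list alone, with Spink4 and the peptide gene Guca2a at the front (log2 fold change -6.17, adjusted p = 0.00214, moved to -4.44 without WT 2 and log2 fold change -5.75, adjusted p = 0.00145, moved to -4.72 without WT 2 and -6.77 without AKSP 1). In that list 2 rose (1 without AKSP 2), Bcas1 and the transcription factor gene Creb3l1 (log2 fold changes 3.63 and 1.17), and the list passed. Camera gave the goblet cell list adjusted p = 0.00111, alternatives from 2.7e-04 up to adjusted p = 0.337 with an estimated correlation. Crypt markers again held genes that fell, such as Olfm4 (log2 fold change -9.29, adjusted p = 2.0e-04, moved to -11.34 without AKSP 2), and genes that rose, such as Tnfrsf19 (log2 fold change 4.96, adjusted p = 4.7e-05), with 3 that rose (5 without WT 2) and 8 that fell of 20. That became 5 and 8 adjusted over the list alone. Camera gave the crypt stem cell list adjusted p = 0.0926, alternatives from 0.0301 up to adjusted p = 0.608 with an estimated correlation, reached at 0.0301 without AKSP 2. Small intestine markers gave 1 that rose (2 without WT 1) and 9 that fell of 14. That became 2 and 9 adjusted over the list alone. Camera gave the small intestine region list adjusted p = 4.5e-04, alternatives from 1.2e-04 up to adjusted p = 0.160 with an estimated correlation. The member that rose was Pdx1, a transcription factor of the upper gut (log2 fold change 1.41).

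Genes of foregut, fetal and wounded epithelium were higher in AKSP than in WT. Muc5ac, the mucin of the stomach surface, had 2 counts over the WT libraries and 75.6 ± 63.4 CPM (SD, n = 3) in AKSP (ratio 3985, 95% counting interval 1103 to 32910), with AKSP libraries that differed widely. Stomach epithelium genes gave 10 that rose, among them Tff1 and Vsig1 (log2 fold changes 5.88 and 5.93), and 1 that fell (0 without WT 1, 0 without WT 3, 0 without AKSP 2 and 0 without AKSP 3), the calpain gene Capn8 (log2 fold change -2.63), of 12, also 10 and 1 adjusted over the list alone. Camera gave the gastric epithelium list adjusted p = 1.7e-04, alternatives from 8.5e-05 up to adjusted p = 0.195 with an estimated correlation. Fetal-like genes rose in 18 of 22 cases and fell in 0. That became 20 and 0 adjusted over the list alone. Camera gave the fetal-like and regenerative epithelium list adjusted p = 5.2e-09, alternatives from 5.3e-10 up to adjusted p = 0.195 with an estimated correlation. Ccn2, a matricellular protein gene and YAP target, went from 1.18 ± 1.15 CPM (SD, n = 3) to 126 ± 34.2 CPM (SD, n = 3) (log2 fold change 7.01, SE 0.79, adjusted p = 1.4e-04, moved to 7.88 without WT 2). YAP and TAZ targets rose in 17 of 21 cases, 0 fell (1 without WT 2), and 18 rose adjusted over the list alone. Camera gave the YAP/TAZ targets list adjusted p = 2.6e-07, alternatives from 9.0e-08 up to adjusted p = 0.0513 with an estimated correlation. ERK output genes rose in 19 of 23 cases and fell in 1, Egr1 (log2 fold change -1.92). That became 21 and 1 adjusted over the list alone. Camera gave the ERK pathway output list adjusted p = 9.3e-08, alternatives from 2.5e-08 up to adjusted p = 0.142 with an estimated correlation. Fosl1 and Plaur, the urokinase receptor gene, had the largest changes (log2 fold change 5.68, adjusted p = 7.8e-06 and log2 fold change 4.33, adjusted p = 1.8e-05). Wnt targets gave 11 that rose and 1 that fell (4 without AKSP 2 and 0 without AKSP 3), Sox4 (log2 fold change -1.31), of 22. That became 13 and 1 adjusted over the list alone. Camera gave the Wnt/beta-catenin targets list adjusted p = 0.00608, alternatives from 0.00288 up to adjusted p = 0.337 with an estimated correlation. Genes of stratified epithelium rose in 8 of 12 cases, 9 adjusted over the list alone, led by the desmoglein gene Dsg3 (log2 fold change 6.75, adjusted p = 1.1e-04), and the list passed. Camera gave the squamous epithelium list adjusted p = 8.3e-04, alternatives from 1.7e-04 up to adjusted p = 0.175 with an estimated correlation. Cell cycle genes gave 13 that rose (8 without AKSP 3) and 0 that fell of 25, also 13 adjusted over the list alone, with the spindle factor Tpx2 going from 76.5 ± 10.8 CPM (SD, n = 3) to 220.2 ± 24.1 CPM (SD, n = 3) (log2 fold change 1.52, adjusted p = 6.0e-04; camera adjusted p = 0.00111, alternatives from 9.8e-05 up to adjusted p = 0.353 with an estimated correlation). Oxidative phosphorylation genes fell in 20 of 22 cases and rose in 0, or 21 and 0 adjusted over the list alone (camera adjusted p = 8.4e-07, alternatives from 3.1e-08 up to adjusted p = 0.337 with an estimated correlation), for example Sdhc (log2 fold change -1.96, adjusted p = 4.4e-04). Without WT 2, where this list was high, 21 members fell and its median log2 fold change went from -1.52 to -1.13.

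Targets of p53, BMP and TGF-beta signalling moved both ways in AKSP vs WT. Targets of p53 gave 6 that rose and 10 that fell of 30, or 6 and 12 adjusted over the list alone, with no call for the list. Camera gave the p53 targets list adjusted p = 0.102, alternatives from 0.0415 up to adjusted p = 0.337 with an estimated correlation, reached at 0.0415 without AKSP 2. Ephx1, an epoxide hydrolase gene, fell (log2 fold change -5.90, adjusted p = 6.7e-05, moved to -6.79 without AKSP 2) and Plk2 rose (log2 fold change 2.55, adjusted p = 6.5e-04). TGF-beta targets gave 7 that rose and 2 that fell of 14, the same adjusted over the list alone. Camera gave the TGF-beta-SMAD targets list adjusted p = 0.0979, alternatives from 0.0471 up to adjusted p = 0.353 with an estimated correlation, reached at 0.0471 with GC and length offsets. BMP targets gave 1 that rose (3 without WT 2) and 2 that fell (1 without WT 1, 1 without WT 3, 1 without A 1, 1 without A 2, 1 without A 3, 0 without AKSP 1 and 0 without AKSP 3) of 11. That became 1 and 1 adjusted over the list alone. Camera gave the BMP-SMAD targets list adjusted p = 0.953, alternatives from 0.677 to 1.00, and adjusted p = 0.974 with an estimated correlation. The member that rose was Smad7, an inhibitor of both pathways (log2 fold change 1.64, adjusted p = 0.00481), and the Notch target Hes1 fell (log2 fold change -1.40, adjusted p = 0.0177, lost at 0.0689 without AKSP 1 and 0.0584 without AKSP 3, range 0.00250 to 0.0689). Over all genes, 6266 of 16698 were called, 3114 higher and 3152 lower (edgeR quasi-likelihood test), and the libraries of AKSP and WT did not overlap for 50.5% of genes against 10% by chance. Which direction held more calls varied with the setting, from 44.8% higher without WT 3 (2524 higher, 3110 lower) to 59.1% with library totals (3555 and 2463). The lower genes numbered 1968 without AKSP 3. Across genes, the fold changes correlated with transcript length at Spearman 0.346. The sex-linked list passed again with 4 members higher and 1 lower of 5, the same adjusted over the list alone. Camera gave the sex-linked list adjusted p = 0.00523, alternatives from 0.00203 up to adjusted p = 0.337 with an estimated correlation. The largest increases included the hair keratin gene Krt27, the ephrin gene Efna5 and the potassium channel gene Kcnq5. These had 0 counts in WT and were at least 1673-fold, at least 709.6-fold and at least 316-fold higher. Of the 14 lists called in AKSP vs WT, 0 kept the call with an estimated correlation, the lowest adjusted p being 0.0513.

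Further genes that met the naming rule in AKSP vs WT had been called in the same direction in A vs WT. Those that fell were Gip (log2 fold change -8.93, adjusted p = 1.6e-04, moved to -7.57 without WT 2 and -9.70 without AKSP 1), Sst (ratio 1774, 95% counting interval 318 to 70140, log2 fold change -10.94, moved to -10.01 without WT 2), Mptx2 (log2 fold change -9.11, adjusted p = 4.6e-04, moved to -9.70 without WT 2, -8.48 without WT 3 and -10.21 without AKSP 1), Gsta1 (log2 fold change -4.18, adjusted p = 1.3e-04), Mmp14 (log2 fold change -6.75, adjusted p = 6.0e-06) and mt-Nd3 (log2 fold change -2.01, adjusted p = 0.0116, moved to -1.35 without WT 2). H2-Ab1 had 0 counts in AKSP, at least 90.2-fold lower. Those that rose were Prox1 (log2 fold change 4.61, adjusted p = 9.6e-04, moved to 5.47 without WT 1 and 3.65 without AKSP 2), Krt4 (log2 fold change 6.27, adjusted p = 1.2e-04, moved to 5.54 without AKSP 1), Ptpn14 (log2 fold change 5.24, adjusted p = 4.9e-06), Col4a1 (log2 fold change 8.25, adjusted p = 7.8e-06), Hspa1b (log2 fold change 3.29, adjusted p = 7.9e-05) and Ptgs1 (ratio 969, 95% counting interval 331 to 4699). Serpine1 rose too (log2 fold change 7.41, adjusted p = 0.00567, moved to 8.68 without WT 3 and 5.08 without AKSP 2, lost at 0.0506 with quality weights, range 4.6e-07 to 0.0506). Ddx3y and Ly6g had 0 counts in WT and were at least 1120-fold and at least 965-fold higher. Other genes that fell were Nrn1, a crypt marker (log2 fold change -8.16, adjusted p = 2.1e-04, moved to -8.82 without AKSP 3), the claudin gene Cldn15 (log2 fold change -6.30, adjusted p = 2.8e-05), Mettl7b of the colon list (log2 fold change -5.55, adjusted p = 1.6e-04, moved to -6.29 without AKSP 2), the immunoproteasome gene Psmb9 (log2 fold change -4.29, adjusted p = 0.00168, moved to -5.23 without AKSP 2) and the glycolytic enzyme gene Eno1 (log2 fold change -1.47, adjusted p = 0.00145). The falls of Cldn15, Mmp14 and Gsta1 were not typical of their lists, which did not pass. Of the epithelial junction and keratin list of Cldn15, 6 rose and 2 fell of 17. The lists of Mmp14 and Gsta1 gave 6 and 3 of 12 and 6 and 5 of 17. Psat1, an enzyme of serine synthesis, and Suz12, a Polycomb subunit, rose (log2 fold change 1.46, adjusted p = 5.8e-04 and log2 fold change 1.55, adjusted p = 0.0183, moved to 2.20 without WT 1).

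Markers of other cell types had group means of at most 11.1 CPM, and none of their 3 lists passed with camera in any comparison. Tek, a receptor of endothelial cells, rose from 0.0675 ± 0.0395 CPM (SD, n = 3) in WT to 2.42 ± 1.24 CPM (SD, n = 3) in A (log2 fold change 5.43, adjusted p = 0.00133), and Tie1, a related receptor, rose from 0.0379 ± 0.0362 CPM (SD, n = 3) to 1.19 ± 0.686 CPM (SD, n = 3) in AKSP (log2 fold change 4.53, adjusted p = 0.00132). Of 6 endothelial markers, 3 rose (1 without WT 3) and 1 fell (0 without WT 1, 0 without WT 3, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1 and 0 without AKSP 2) in A vs WT, with 3 and 1 adjusted over the list alone. Camera gave the endothelial cell list adjusted p = 0.482, alternatives from 0.346 up to adjusted p = 0.661 with an estimated correlation. In AKSP vs WT 3 rose and 1 fell (0 without WT 1, 0 without WT 3, 0 without A 3, 0 without AKSP 1, 0 without AKSP 2 and 0 without AKSP 3), with 3 and 1 adjusted over the list alone. Camera gave the endothelial cell list adjusted p = 0.206, alternatives from 0.125 to 0.344, and adjusted p = 0.339 with an estimated correlation. The member that fell in both was Pecam1, an adhesion molecule (log2 fold changes -2.09 and -1.91). Col1a2, a collagen of fibroblasts, had 0 counts in WT and was at least 13.8-fold higher in AKSP. Of 3 fibroblast markers, 1 rose and 1 fell in A vs WT, the same adjusted over the list alone. Camera gave the fibroblast list adjusted p = 0.972, alternatives from 0.763 to 0.994, and adjusted p = 0.984 with an estimated correlation. In AKSP vs WT 2 rose (1 without WT 1 and 1 without AKSP 2) and 1 fell, with 2 and 1 adjusted over the list alone. Camera gave the fibroblast list adjusted p = 0.602, alternatives from 0.497 up to adjusted p = 0.739 with an estimated correlation. The receptor gene Pdgfrb fell in both (log2 fold changes -3.91 and -4.31). Of 5 leukocyte markers, 1 rose (0 without WT 1, 0 without WT 2, 0 without WT 3, 0 without A 2 and 0 without A 3) and 1 fell (0 without WT 1, 0 without WT 3, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1 and 0 without AKSP 3) in A vs WT, with 1 and 1 adjusted over the list alone. Camera gave the leukocyte list adjusted p = 0.791, alternatives from 0.637 to 0.999, and adjusted p = 0.850 with an estimated correlation. In AKSP vs WT 3 rose (1 without WT 3) and 2 fell (1 without WT 2, 1 without WT 3, 1 without A 1, 1 without A 2, 1 without A 3, 1 without AKSP 1 and 1 without AKSP 3), with 3 and 2 adjusted over the list alone. Camera gave the leukocyte list adjusted p = 0.779, alternatives from 0.623 to 0.931, and adjusted p = 0.859 with an estimated correlation. The integrin gene Itgam was among those that fell (log2 fold change -2.45, adjusted p = 0.00355). In AKSP vs A, for the endothelial markers 0 rose (1 without WT 2), for the leukocyte markers 0 rose (1 without WT 2, 1 without A 1 and 1 with the replicate block) and for the fibroblast markers 0 rose, with 0, 2 and 1 adjusted over the list alone, and 0 fell in each. With GC and length offsets 1 endothelial and 1 leukocyte marker rose.

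AKSP vs A compares tumoroids that the labels give a mutant Kras allele and knockouts of Smad4 and Trp53 as well with tumoroids engineered at Apc. These 3 alterations occur together, and no library separates them from each other or from any other difference between the A and AKSP tumoroids. Of 5 sex-linked genes, 0 rose and 1 fell in AKSP vs A, and the reads of Nnt shifted between its 2 gene models, as given below. The clearest group was the p53 targets, which fell. Eda2r, a receptor gene of the TNF family, went from 49.7 ± 11.3 CPM (SD, n = 3) in A to 0.0467 ± 0.0299 CPM (SD, n = 3) in AKSP (log2 fold change -9.95, SE 0.96, adjusted p = 8.8e-04, moved to -10.54 without AKSP 3), and Ephx1 from 135 ± 27.7 CPM (SD, n = 3) to 3.31 ± 2.65 CPM (SD, n = 3) (log2 fold change -5.36, SE 0.56, adjusted p = 0.00104, moved to -6.25 without AKSP 2). Mdm2, Ccng1 and the pleckstrin-domain gene Phlda3 fell with them (log2 fold changes -1.68, -2.79 and -3.86). Of 30 targets 0 rose and 12 fell (6 without A 2, 6 without AKSP 1 and 7 without AKSP 3), or 20 adjusted over the list alone. Camera gave the p53 targets list adjusted p = 1.2e-13, alternatives from 4.0e-15 up to adjusted p = 0.0217 with an estimated correlation. It was the 1 list of the 11 called in AKSP vs A that kept its call with an estimated correlation. AKSP 2 departed from AKSP 1 and AKSP 3 in part of this list. Cdkn1a, the cell cycle inhibitor that p53 induces, stood at 28.2, 190.5 and 26.9 CPM in AKSP 1, AKSP 2 and AKSP 3 against 255 ± 50.7 CPM (SD, n = 3) in A and was not called (log2 fold change -1.64, adjusted p = 0.235).

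**Figure D4:**
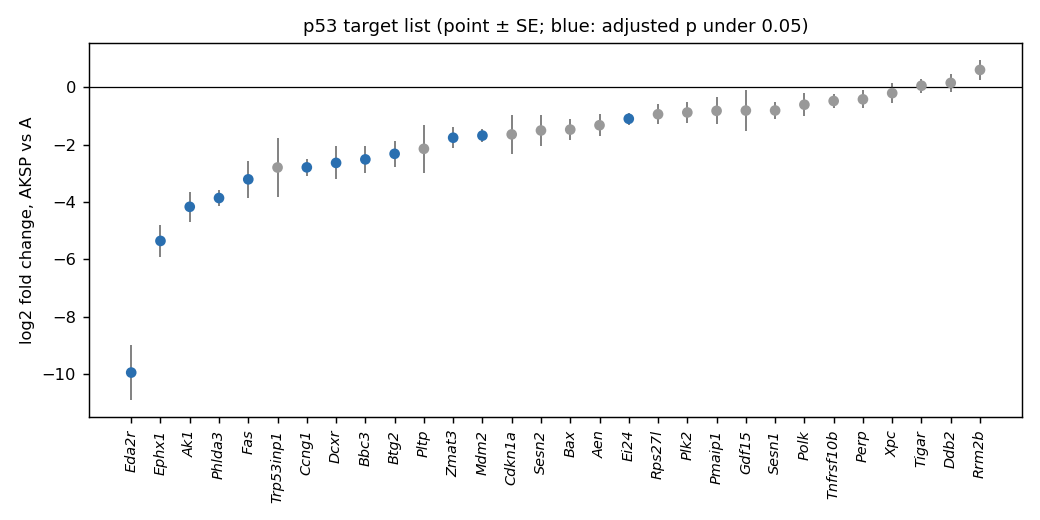
Log2 fold change in AKSP vs A (vertical axis, point ± SE) of each of the 30 tested p53 targets, ordered by value, with called genes in blue. Eda2r was lowest at -9.95, and the 12 called genes all lay below 0.

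Some markers of differentiated cells were lower still in AKSP than in A, while most members of these lists were not called. Enteroendocrine markers gave 0 that rose and 6 that fell (10 without WT 2, 3 without A 1, 2 without A 2, 2 without A 3 and 2 without AKSP 3) of 22, or 13 adjusted over the list alone. Camera gave the enteroendocrine cell list adjusted p = 6.4e-08, alternatives from 1.8e-09 up to adjusted p = 0.598 with an estimated correlation. Neurog3, the transcription factor that starts endocrine differentiation, fell from 10.3 ± 3.25 CPM (SD, n = 3) to 1.48 ± 0.582 CPM (SD, n = 3) (log2 fold change -2.80, adjusted p = 0.00809). Paneth cell markers gave 0 that rose and 4 that fell (12 without WT 2, 2 without A 1, 1 without A 2, 2 without A 3, 2 without AKSP 2, 1 without AKSP 3 and 8 with the replicate block) of 17, or 11 adjusted over the list alone (camera adjusted p = 2.2e-07, alternatives from 7.9e-09 up to adjusted p = 0.598 with an estimated correlation), with Ang4, an antimicrobial angiogenin, at 11.1 ± 7.12 CPM (SD, n = 3) in A and 0.487 ± 0.252 CPM (SD, n = 3) in AKSP (log2 fold change -4.51, adjusted p = 0.00647, moved to -3.85 without A 2). Crypt stem cell markers gave 0 that rose and 3 that fell (6 without WT 2, 1 without A 2, 1 without A 3, 1 without AKSP 1, 1 without AKSP 3 and 5 with the replicate block) of 20, or 5 adjusted over the list alone. Camera gave the crypt stem cell list adjusted p = 0.00494, alternatives from 1.1e-04 up to adjusted p = 0.598 with an estimated correlation. Clca3b, of the chloride channel regulator family, fell from 422 ± 97.7 CPM (SD, n = 3) to 33.1 ± 10.3 CPM (SD, n = 3) (log2 fold change -3.67, SE 0.32, adjusted p = 6.5e-04). Enterocyte markers gave 2 that rose and 6 that fell (2 without A 1, 2 without A 2, 2 without AKSP 1 and 1 without AKSP 3) of 26. That became 2 and 11 adjusted over the list alone. Camera gave the enterocyte list adjusted p = 0.00139, alternatives from 1.2e-05 up to adjusted p = 0.598 with an estimated correlation. The members that rose were Alpi, intestinal alkaline phosphatase (log2 fold change 4.31, adjusted p = 0.00373), and the brush border protease gene Mep1b (log2 fold change 2.47). Muc13, a transmembrane mucin of the goblet cell list, fell (log2 fold change -3.02, adjusted p = 0.00755). The goblet cell list passed with 1 that rose (2 without WT 2, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1, 0 without AKSP 2 and 0 without AKSP 3), Bcas1, and 1 that fell (2 without WT 1 and 4 without WT 2). That became 2 and 4 adjusted over the list alone. Camera gave the goblet cell list adjusted p = 0.0208, alternatives from 0.00311 up to adjusted p = 0.624 with an estimated correlation, lost at 0.126 without AKSP 3.

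Other genes rose in AKSP over A. Muc5ac went from 0.0682 ± 0.0321 CPM (SD, n = 3) to 75.6 ± 63.4 CPM (SD, n = 3) (log2 fold change 10.06, SE 0.87, adjusted p = 6.5e-04, moved to 9.17 without AKSP 1), with AKSP libraries that differed widely. Stomach epithelium genes gave 4 that rose (2 without A 2) and 1 that fell, the gland mucin gene Muc6 (log2 fold change -4.27), of 12. That became 5 and 1 adjusted over the list alone. Camera gave the gastric epithelium list adjusted p = 0.0497, alternatives from 0.0211 up to adjusted p = 0.598 with an estimated correlation, lost at 0.0803 without WT 1, 0.114 without WT 2, 0.0571 without WT 3, 0.0936 without A 2, 0.0863 without AKSP 1, 0.0584 with relative log expression factors, 0.0816 with the replicate block and 0.0782 with GC and length offsets. ERK output genes gave 3 that rose (6 without WT 2 and 1 without A 2) and 0 that fell (1 without AKSP 2) of 23. That became 6 and 1 adjusted over the list alone. Camera gave the ERK pathway output list adjusted p = 0.00573, alternatives from 0.00204 up to adjusted p = 0.598 with an estimated correlation. Spry4, a feedback inhibitor of this pathway, went from 0.810 ± 0.153 CPM (SD, n = 3) to 9.05 ± 3.71 CPM (SD, n = 3) (log2 fold change 3.48, SE 0.42, adjusted p = 0.00188), and the phosphatase gene Dusp6 rose too (log2 fold change 1.40). Cell cycle genes passed as a list with 0 members called, and 6 higher without WT 2. Camera gave the proliferation list adjusted p = 0.00146, alternatives from 1.8e-05 up to adjusted p = 0.598 with an estimated correlation. BMP targets gave 0 that rose, 1 without WT 2, and 4 that fell (2 without A 2, 1 without A 3, 2 without AKSP 1 and 1 without AKSP 3) of 11. That became 2 and 4 adjusted over the list alone. Camera gave the BMP-SMAD targets list adjusted p = 0.119, alternatives from 0.0234 up to adjusted p = 0.624 with an estimated correlation, reached at 0.0234 without A 1. Those that fell were Id2, Id3, Smad9 and Atoh8.

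TGF-beta targets did not pass as a list in AKSP vs A, with 1 that rose (2 without WT 1, 2 without WT 2, 2 without WT 3, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1, 0 without AKSP 3 and 0 with the replicate block), Pmepa1, and 0 that fell (1 without WT 1, 1 without WT 2, 1 without WT 3 and 1 without A 3) of 14, while 2 and 2 did so adjusted over the list alone. Camera gave the TGF-beta-SMAD targets list adjusted p = 0.474, alternatives from 0.330 to 0.963, and adjusted p = 0.701 with an estimated correlation. Nor did Wnt targets. In that list 1 rose (2 without WT 2), the signalling gene Bmp4 (log2 fold change 5.33), and 1 fell (0 without WT 1, 3 without WT 2, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1, 2 without AKSP 2, 0 without AKSP 3 and 0 with the replicate block), Sox4, of 22. That became 2 and 5 adjusted over the list alone. Camera gave the Wnt/beta-catenin targets list adjusted p = 0.365, alternatives from 0.114 up to adjusted p = 0.701 with an estimated correlation. Fetal-like genes did not pass either, with 0 that rose and 4 that fell (2 without A 1, 2 without A 2, 2 without A 3, 2 without AKSP 1 and 2 without AKSP 3) of 22. That became 0 and 4 adjusted over the list alone. Camera gave the fetal-like and regenerative epithelium list adjusted p = 0.124, alternatives from 0.0422 up to adjusted p = 0.675 with an estimated correlation, reached at 0.0422 without AKSP 1. Basp1, of the fetal-like list, and the basal keratin gene Krt5 fell (log2 fold change -5.29, adjusted p = 0.00351 and log2 fold change -5.46, adjusted p = 0.00237), and Pdx1 rose (log2 fold change 3.34, adjusted p = 0.00104). The largest increases were in Zic5, a zinc finger factor gene (ratio 2702, 95% counting interval 485 to 106800), and in St8sia4, Bcat1 and Rdx, which encode a sialyltransferase, an amino acid transaminase and the membrane linker radixin (log2 fold changes 8.20, 7.68 and 7.11, the first 7.50 without AKSP 2). The largest decreases were in Mdfic, a transcription regulator gene with 0 counts in AKSP (at least 384-fold lower), Ifitm3, an antiviral membrane protein gene (ratio 1103, 95% counting interval 305 to 9114), the carboxylesterase gene Ces2f (ratio 916, 95% counting interval 253 to 7566), and Dglucy and Zfp750 (log2 fold changes -8.13 and -7.28, Dglucy -10.56 without AKSP 2). Nnt, which also met the rule, has 2 overlapping gene models on chromosome 13, and its change is uncertain: 1 model rose from 0 to 17.6 ± 7.90 CPM (SD, n = 3), the other stood at 45.1 ± 5.67 CPM in A and 12.9 ± 2.26 CPM in AKSP, and their sum was 45.1 ± 5.67 and 30.5 ± 6.30 CPM.

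Over all genes, AKSP vs A called 961 of 16698, 397 higher and 564 lower (edgeR quasi-likelihood test), and the libraries did not overlap for 34.5% of genes against 10% by chance. The count was 1925 without WT 2, 458, 402 and 418 without A 1, A 2 and A 3, and 525 and 397 without AKSP 1 and AKSP 3. The higher and lower genes numbered 809 and 1116 without WT 2, 159 and 299 without A 1, 152 and 250 without A 2, and 145 and 273 without A 3. Without AKSP 1 they numbered 235 and 290, and without AKSP 3 176 and 221. The calls of 11 further genes that the naming rule took, all lower in AKSP except Bcas1, Emp1 and Pmepa1, were lost when 1 of several libraries was left out. Their log2 fold changes were -1.44 for Sox4, -4.63 for Aqp4 (-6.44 without AKSP 2), -3.51 for Dpp4 (-4.57 without AKSP 2), 1.43 for Bcas1, -6.13 for Defa20 (-7.97 without AKSP 1), -2.96 for Nts, -3.17 for Ly6d (-3.88 without AKSP 2), 1.48 for Emp1, -2.02 for Id3, -1.32 for Id2 and 0.98 for Pmepa1. Their adjusted p was 0.05 or more without WT 1 for Sox4 (0.0567), without A 1 for Sox4, Aqp4, Bcas1, Defa20, Nts, Ly6d and Pmepa1 (0.0654 to 0.120), without A 2 for Sox4, Aqp4, Bcas1, Defa20, Nts, Ly6d, Emp1, Id3, Id2 and Pmepa1 (0.0624 to 0.163), without A 3 for Sox4, Aqp4, Bcas1, Defa20, Nts, Ly6d, Emp1, Id3, Id2 and Pmepa1 (0.0580 to 0.146), without AKSP 1 for Sox4, Aqp4, Dpp4, Bcas1, Nts, Ly6d, Emp1, Id3, Id2 and Pmepa1 (0.0566 to 0.128), without AKSP 2 for Bcas1, Defa20, Nts and Id3 (0.0672 to 0.112) and without AKSP 3 for Sox4, Aqp4, Bcas1, Defa20, Nts, Ly6d, Emp1, Id3, Id2 and Pmepa1 (0.0509 to 0.164). With the replicate block, Sox4, Nts, Id3 and Pmepa1 were also lost, at adjusted p = 0.0775, 0.0665, 0.0711 and 0.0657. Sox4 was lost at 0.0938 with library totals and Nts at 0.0528 with a mean of at least 1 CPM. Pmepa1 was lost at 0.0952 with no expression filter, at 0.0543 with GC and length offsets and at 0.0882 with these offsets and the block. Over all their alternatives, the adjusted p of these 11 genes ran from 3.8e-07 to 0.164. Oxidative phosphorylation passed as a list in AKSP vs A with 0 that fell (8 without WT 2) and 0 that rose. Camera gave the oxidative phosphorylation list adjusted p = 0.0275, alternatives from 0.00118 up to adjusted p = 0.624 with an estimated correlation, lost at 0.0825 without A 1, 0.05001 without A 2, 0.0858 without AKSP 2, 0.0605 without AKSP 3 and 0.0640 with GC and length offsets. Interferon response genes passed too. Camera gave the interferon response and MHC class I list adjusted p = 0.00862, alternatives from 1.3e-05 up to adjusted p = 0.624 with an estimated correlation, lost at 0.0936 without A 2 and 0.0681 without AKSP 1. In that list 0 rose (1 without WT 2) and 1 fell (3 without WT 2, 0 without A 1, 0 without A 2, 0 without A 3, 0 without AKSP 1, 3 without AKSP 2 and 0 without AKSP 3). That became 1 and 3 adjusted over the list alone. The member that fell was Stat1, an interferon-response factor (log2 fold change -1.37).

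The 2 comparisons with WT shared many genes. Of 16698 genes, 1833 were higher and 1644 lower in both A and AKSP, where independent lists of the same sizes would share 409.7 and 356.2, and 38 were called in opposite directions. The shared total of 3477 was 2206 without A 3. The log2 fold changes correlated across genes with Pearson r = 0.869 and a covariance of 4.46, beside 0.541 and 0.237 in 20 simulations of unchanged groups against the same WT libraries, in which at most 0 genes were called in both. Genes are not independent replicates, and part of the excess may come from the shared WT libraries, since 3 libraries cannot be split with 2 in each part. Among genes called in both A vs WT and AKSP vs A, 157 were higher in A than in WT and then lower in AKSP, as were Eda2r, Mdm2, Ccng1 and Phlda3, and 67 were lower and then higher, as was Pdx1 (independent lists, 74.2 and 44.9). The other 127 and 161 moved further up or further down (independent lists, 52.2 and 63.7). The 224 opposite calls were 368 without WT 2, 119, 105 and 101 without A 1, A 2 and A 3, and 138 and 111 without AKSP 1 and AKSP 3. The correlation of these fold changes was r = 0.0497 with a covariance of 0.127. Simulations drawn around the A levels averaged -0.479 and -0.180, since A stands on opposite sides of the 2 comparisons.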

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

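The choices other than those named above as added later were made before the data were examined, and no called gene that is named, and no called list, turned its direction under any alternative run. The direction with more calls did turn in A vs WT and AKSP vs WT, as the report gives, and in AKSP vs A the lower genes were more numerous in each setting. The count in A vs WT (4084) ran from 2503 to 4987 when 1 library was left out, and that in AKSP vs WT (6266) from 4300 to 6950. AKSP vs A (961) ran from 397 (without AKSP 3) to 1925 (without WT 2), and gave 1836 with only the 2 groups fitted, 1824 with DESeq2 and 5016 with sample quality weights, which set WT 2 to 0.154 and AKSP 2 to 0.416. DESeq2 shared 4007, 6148 and 952 genes with the edgeR calls of A vs WT, AKSP vs WT and AKSP vs A. The 3477 genes shared by the comparisons with WT ran from 2206 to 4397, and the 224 opposite calls from 101 to 368, with 143 at a mean of at least 1 CPM. No WT library enters the AKSP vs A contrast, but the WT libraries enter the spread that all groups share. Its 961 calls became 1925 without WT 2 and 1836 with only the 2 groups fitted, so that count rests in part on the spread of WT. The cause of the other moves was not tested, apart from fewer libraries or genes by construction. Offsets for GC content and length gave 4441, 6512 and 1328 calls (1205 with the block), of which 3636, 5400 and 927 were shared. Recovered reads gave the same 4084, 6266 and 961, which was fixed in advance, since they equal the rounded counts for at least 99.996% of values. The replicate block gave 795 calls in AKSP vs A, 710 of them shared. Among the named genes and lists it changed no call beyond those given in the report. Because all 9 libraries entered that fit, its replicate effects rest on WT as well. A block on the A and AKSP libraries alone was not fitted, so these calls do not measure that pairing by itself. WT shares only a number with the tumoroids: same-numbered libraries correlated at 0.123, -0.014 and 0.075 in A vs WT and -0.094, -0.054 and -0.026 in AKSP vs WT, and not every library correlated best with its own number. The same block fit gave 3905 and 6102 calls in these comparisons, and moved Trp53 in A vs WT to adjusted p = 0.0403 and the colon list in AKSP vs WT to 0.0391. With an estimated correlation, 38 of the list calls were lost. The estimate alone does not explain such changes. For YAP/TAZ targets in A vs WT it was 0.0088, below the preset 0.01. The camera p of that list still rose from 4.2e-10 to 7.4e-04. Of the named gene settings, 2942 stayed on the same side of the threshold, whatever the size of the fold change, 7 gained a call and 92 lost one. Recovered reads made up 144 of the 2942. The simulation, in which depth was not varied, recovered at most 6% of genes at a log2 fold change of 1. It gave only 124, 131 and 139 calls, against 4084, 6266 and 961 in the data. Its adjusted p was therefore stricter, and its recovery may be too low for these comparisons.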

Other observations

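Members of several gene families moved in the same direction. This search over 351 symbol families (2106 hypergeometric tests, 44 passing) was made after the results were seen and is exploratory. All 13 tested members of the Cyp2c family of cytochrome P450 genes, 2 of them pseudogenes, were lower in A and in AKSP than in WT. The carboxylesterase family Ces had all 12 genes lower in AKSP than in WT and 8 of 12 lower in AKSP than in A. Keratins (Krt) were higher in A than in WT for 17 of 23, with 1 lower, as were 10 of 12 Serpinb protease inhibitors and 9 of 12 annexins (Anxa). Of the Paneth cell defensins (Defa) 20 of 22 were lower in AKSP than in WT and 8 lower than in A, the latter 21 without WT 2. Ribosomal protein genes were lower in AKSP than in WT for 26 of 31 Rps and 29 of 47 Rpl, with 19 and 17 under GC and length offsets. Their median log2 fold changes were -1.78 and -1.43, and -0.80 and -0.59 without WT 2. Respiratory chain families also had smaller medians without WT 2: Cox from -1.91 to -0.75 and Ndufa from -1.87 to -1.02 in AKSP vs WT, and Cox from -1.61 to -0.83 in A vs WT.

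WT 2 stood apart from WT 1 and WT 3, and no biological explanation was tested. Before thinning, WT 1 and WT 3 detected 22072 and 21167 genes against 17690 in WT 2. Thinned to the depth of WT 2, they detected 18898 on average (19353 and 18442) against 17678. Lower depth thus accounts for the larger part of the gap in genes detected. WT 1 and WT 3 still detected 9.48% and 4.32% more, so whether depth accounts for the whole gap stayed undecided. Transcript length went with the deviation of WT 2 at a Spearman correlation of -0.472, so a length bias, such as RNA breakage, could account for part of it. The Paneth cell list stayed high at 1.79 (2.34 before) after a trend on GC content and length, fitted across genes, was removed. That average trend accounts for only part of the deviation of those genes. The length test was written after the deviation was seen, and a condition on spread was added to the Paneth rule after its result.

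Apc transcript was higher in A and AKSP than in WT, and the design offers a biological reason, the engineered allele, that was not tested. With GC and length offsets the log2 fold change in A vs WT was 1.24 (SE 0.41, adjusted p = 0.0499), and without WT 2 it was 1.80 (SE 0.68, adjusted p = 0.0886). In A vs WT neither value settles whether a bias of single libraries may produce the rise. Deviations from the group mean correlated with GC content at Spearman -0.500 in A 1, 0.365 in A 2, 0.335 in A 3 and 0.424 in WT 3. Apc stood at 176, 48.0 and 66.9 CPM in A 1, A 2 and A 3, and its log2 fold change was 1.27 without A 1. In AKSP vs WT the rise was 1.53 (SE 0.42, adjusted p = 0.0149) with offsets and 2.23 (adjusted p = 0.0331) without WT 2, and Apc was called in all 21 alternatives, the highest adjusted p being 0.0331. The test without WT 2 was written after results were seen, and its reading moved to undecided when the condition on spread was added.

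AKSP 2 stood apart from AKSP 1 and AKSP 3, and genotype offers no biological explanation. Admixed A cells could explain high Cdkn1a only at 71.5% of the library, while 4 genes nearly absent from the other AKSP libraries (Dglucy, Tm4sf4, Ces2e and Eda2r) implied a median of 0.849% (-0.0705% to 12.5%). GC content and length leave the hypoxia list at 2.36 (quartiles 1.28 to 2.96), with a condition on spread added after the result. The list deviated by 2.43 (log2), above all 10000 random lists. It was picked as the largest of 36 deviations, and random lists lack the correlation between its genes (0.783), so this rank is no support of its own. A low-oxygen culture state remains a candidate only. In A 2 the list deviated by 0.965. The admixture and hypoxia tests were written after results were seen.

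Cdkn2a, a cell cycle inhibitor gene chosen after its values were seen, stood at 1.37 ± 2.24 CPM (SD, n = 3) in WT. That mean came mostly from WT 2, with 0.0722, 3.95 and 0.0828 CPM in WT 1, WT 2 and WT 3, and the fold against WT depends on it. Cdkn2a stood at 5.34 to 7.41 CPM over the A libraries and 106.6 ± 10.5 CPM (SD, n = 3) in AKSP. By the edgeR test its log2 fold change was 4.02 in AKSP vs A (adjusted p = 0.064) and 6.76 in AKSP vs WT (adjusted p = 0.0030). The A and AKSP libraries did not overlap, with 98.3 to 118.5 CPM over the AKSP libraries. The spread in this test is shared with WT, so WT 2 may weigh on the missed call, which was not tested. Genes on chromosome 19 had a median log2 fold change of 0.37 in AKSP vs A (0.45 with offsets), and those on chromosomes 7 and 10 -0.26 and -0.23 (-0.15 and -0.15 with offsets). Splits of 6 libraries into 3 and 3 number 10, so a share is never under 0.1: 1 split, the real one, gave as many calls in each comparison. The real counts were 4084, 6266 and 961 and the highest others 0, 0 and 1; in AKSP vs A the 3 other splits that part 3 pairs called 0, 0 and 1 genes, and the 6 that part 1 pair called 0.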
